A study of Mus musculus with 2 samples.

How the data were processed

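RNA longer than 200 nt was extracted from the intestine of 2 newborn B6NCrl mice, littermates of age 0 days whose sex was not collected, and libraries were made from 10 ng of RNA with exogenous spike-in transcripts added, per the labels. Extraction used the mirVana kit and the library protocol cites the manual of the SMARTer Ultra Low kit, per the labels. The labels number the 2 libraries as biological replicates 1 and 2, named pup 1 and pup 2 here, and both form 1 group. Which segments of the intestine were dissected is not given in the sources used here.

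The authors deposited 1 gene table and 1 transcript table per library, with 69691 and 129984 features. Each table gives expected counts, which are estimated read counts that need not be whole because reads shared between features are divided, and posterior mean estimates of them, per the file headers. The deposited TPM and FPKM values were scaled by the authors to effective length and to the total over all features, spike-ins and mitochondrial genes included. The deposited interval bounds of TPM (coverage level not stated, handled as a signal) were not used here. The deposited transcript tables also give each transcript's share of its gene in percent. The assembly was mm10 with the GENCODE M4 annotation, per the text file deposited with the tables. The aligner, the quantifier, their versions and the use of strand are not given in the sources used here, and the column names are those of RSEM output. Dividing shared reads makes values of near-identical copies uncertain, such as the adult globin pairs, defensins, U3 RNA copies, histones and mitochondrial genes with nuclear copies. Without strand, overlapping genes on opposite strands such as Xist and Tsix or Hoxa11 and its antisense partner can share reads. Overlapping genes such as Hoxa9 and Hoxa10 can share reads whatever the use of strand.

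Gene names, biotypes and positions came from GENCODE M21 on GRCm38, the same assembly as mm10, matched by gene identifier without version for 42462 of 43346 Ensembl genes (98.0%). The 884 genes without a match took 0.113% and 0.121% of the counts in pups 1 and 2, stayed in all totals, and carry no symbol. The 26248 tRNA features (11 and 11.03 reads) and 97 spike-in features were left out of gene-level comparisons. The total expected count over genes was 44568095 in pup 1 and 34797451 in pup 2, with 23080 and 22924 genes with a read. A gene at 0 can hide up to 3 counts, which is 0.0673 and 0.0862 CPM (counts scaled to library size).

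Gene lists, gene pairs and contrasts, the rule for named genes and the alternatives were fixed before the data were examined, 55 lists with 775 members in all, of which 6 were not measured. Named were the 4 highest members of each list and up to 4 of those under 0.1 TPM in both pups, the 15 nuclear protein-coding genes with the highest mean TPM, all genes of the pairs and the HOX genes at 1 TPM or more in both pups. Also named were the 10 highest and 10 lowest between-pup ratios among genes over 2-fold apart with a summed count of 50 or more and a symbol other than a predicted-gene name, members of lists outside the 1st or 99th percentile, and the sex-linked list. Some genes that meet this rule are not reported here. Further genes are said to have been chosen after their values were seen.

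A gene was called detected at 1 TPM or more in both pups. Contrasts of lists are differences between the medians over members of log2(TPM + 0.1), and pairs are log2 ratios of TPM + 0.1, each computed per pup and given as mean ± SD (n = 2). Between-pup ratios used expected counts rounded to whole numbers and effective library sizes from the TMM method of edgeR 4.0.16 in R 4.3.3. Exact (Clopper-Pearson) 95% intervals of the ratio came from SciPy 1.17.1, and a gene was counted as over 2-fold apart if its interval lay wholly above 2 or below 0.5 at a summed count of 10 or more. List ratios are medians of log2 CPM (prior count 2), placed among 10000 random lists of the same size matched on mean expression in 20 bins. The common biological coefficient of variation (BCV) came from edgeR with an intercept alone, on genes with a count of 10 or more in both pups. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

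The methods were tested on simulated data made from the real means and library sizes. For genes over 2-fold apart, among 19074 genes with 200 changed, the rule called 0 of 50 at 1.5-fold, 82% at 3-fold, 98% at 6-fold and 100% at 12-fold, with 1 false call. For list ratios over 23665 genes, 4 of 100 lists without a change fell outside the 1st to 99th percentile and 20 of 20 lists raised 1.5-fold were called. Genes were simulated independently of each other, and lists were not raised by less than 1.5-fold, so power at smaller list ratios is not shown. For the BCV, a true value of 0.1 was estimated as 0.101 over 17189 genes without changed genes and as 0.153 over 17183 with 200 changed ones, so strongly differing genes raise it.

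Alternatives were other detection thresholds and units, posterior mean estimates, RLE size factors, scaling on the spike-in total, other filters on low counts, protein-coding genes alone, a 1.5-fold threshold, log2(TPM + 1), a pseudocount of 1 TPM, means over members, members at 1 TPM or more, CPM without length normalisation, stricter transcript filters and each pup left out. Removal of the gene-length trend from list ratios, as medians in 20 bins of length with interpolation, was added after the data were seen.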

Results

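RNA longer than 200 nt was measured in the intestine of 2 newborn mice (age 0 days) of the B6NCrl strain, littermates, with 1 library per pup. Both libraries belong to 1 group, so the design asks what this tissue expresses at birth and how far littermates differ. The deposited expected counts summed over genes to 44568095 in pup 1 and 34797451 in pup 2. Values are given in TPM, the deposited length-normalised transcript abundance, as mean ± SD over the 2 pups (n = 2), unless each pup's value is given, and no p-value is given, since an exact sign-flip test of 2 values cannot go below 0.5. At 1 TPM or more in both pups, 13870 genes were detected, 12691 of them protein-coding. Of the protein-coding nuclear genes, 86 exceeded 1000 TPM in both pups. Intervals and floors here cover counting error only, since reads without molecular identifiers are not independent molecules.

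Genes of fat absorption were among the most abundant nuclear protein-coding genes of the newborn intestine. Apoa4 (ENSMUSG00000032080.6, chromosome 9, 46240696 to 46243459), an apolipoprotein of chylomicrons, stood at 23927 ± 2296 TPM, and the nearby Apoa1 (ENSMUSG00000032083.8, chromosome 9, 46228580 to 46230466), the main protein of high-density lipoprotein, at 23008 ± 305 TPM. Fabp2 (ENSMUSG00000023057.5, chromosome 3, 122895072 to 122899506) and Fabp1 (ENSMUSG00000054422.7, chromosome 6, 71199827 to 71205023), which bind fatty acids in the enterocyte cytoplasm, reached 12393 ± 611 and 12244 ± 411 TPM. Apoc2, the activator of lipoprotein lipase, reached 9596 ± 687 TPM, Apoc3, its inhibitor, 6609 ± 483 TPM, and Rbp2, the retinol-binding protein of enterocytes, 6081 ± 297 TPM. Coordinates here and below are 1-based on GRCm38, the build named mm10 in the files. All 18 genes of the fat absorption list were at 1 TPM or more in both pups, with a median of 654 ± 2.58 TPM. They included Dgat2 and Mogat2, which build triglyceride (1314 ± 48.1 and 307 ± 22.2 TPM), and Mttp, which loads it onto apolipoprotein B (772 ± 38.8 TPM). The other members of the 15 nuclear protein-coding genes with the highest mean TPM were the ferritin chains Ftl1 (10976 ± 469 TPM) and Fth1 (5922 ± 161 TPM), Actb (8357 ± 259 TPM), the secreted glutathione peroxidase Gpx3 (5398 ± 67.2 TPM), the trypsin inhibitor Spink1 (3980.4 ± 195 TPM), Tmsb4x (3444 ± 224 TPM), Prap1 (3412 ± 19.3 TPM) and Ppia (3207 ± 259.6 TPM). The fat list stood 11.2-fold (log2 3.48 ± 0.089) above the carbohydrate list. This and later contrasts of lists compare the median of log2(TPM + 0.1) over members within each pup, which for a list with an even number of genes differs from the log of its median TPM. In TPM, Apoa4 and Apoa1 differed by less than the spread between pups (log2 0.053 ± 0.12), and without length normalisation their log2 ratio was 0.93.

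The absorptive epithelium carried the genes of the suckling period and little of those that rise at weaning. Lactase (Lct, ENSMUSG00000026354.8, chromosome 1, 128284756 to 128328318), which splits milk sugar, stood at 102 ± 9.27 TPM, against 2.35 ± 0.170 TPM for sucrase-isomaltase (Sis, ENSMUSG00000027790.10, chromosome 3, 72888557 to 72967863) and 1.83 ± 0.233 TPM for trehalase (Treh), a ratio of 41.8-fold (log2 5.39 ± 0.23) and 53.1-fold (log2 5.73 ± 0.044). Ass1, an arginine synthesis enzyme, was at 415 ± 30.0 TPM and Arg2, an arginase of later life, at 0.815 ± 0.0212 TPM, a ratio of 454-fold (log2 8.83 ± 0.071). Fcgrt, the neonatal receptor that carries maternal IgG across the epithelium, reached 2365 ± 194 TPM, and the lysosomal enzymes Ctsl and Ctsz reached 809 ± 59.1 and 691 ± 35.2 TPM. All 18 suckling-type genes were at 1 TPM or more in both pups, and that list stood 23.0-fold (log2 4.52 ± 0.022) above the adult-type list. Adult-type members were not all low: they included Otc (37.4 ± 4.14 TPM), Xdh (22.7 ± 1.77 TPM) and the fructose transporter Slc2a5 (20.3 ± 1.73 TPM), whereas Arg2 and Cyp3a11 (0.220 ± 0.0141 TPM) were under 1 TPM.

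Brush-border genes for sugars and peptides were expressed together. The glucose transporter Slc5a1 stood at 129 ± 3.35 TPM and Khk, which phosphorylates fructose, at 72.5 ± 5.16 TPM. Of the protein digestion list, 12 of 12 genes passed 1 TPM in both pups, among them the cystine transporter subunit Slc7a9 (194 ± 18.9 TPM) and the peptidases Anpep (166 ± 3.20 TPM) and Mep1a (121 ± 3.29 TPM). Genes of ketone synthesis and fatty acid oxidation had a median of 165 ± 7.11 TPM. Of these, Acadl reached 491 ± 2.25 TPM, Hadhb 326 ± 16.0 TPM and Bdh1 256 ± 4.57 TPM. The general epithelial list was led by Lgals4 (1927 ± 49.2 TPM), Cldn7 (1073 ± 54.5 TPM), Epcam (875 ± 19.8 TPM) and Krt8 (863 ± 60.3 TPM). Among 14 junction genes, all of them at 1 TPM or more in both pups, Cldn2 followed Cldn7 at 150.2 ± 6.30 TPM, with Cldn3 at 85.3 ± 11.6 TPM and F11r at 62.8 ± 5.89 TPM.

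Of the secretory lineages, goblet and enteroendocrine genes stood above most Paneth genes. Tff3, a trefoil peptide of goblet cells, stood at 1706 ± 92.9 TPM, the guanylate cyclase activator Guca2a at 1659.9 ± 98.4 TPM, Spink4 at 413 ± 108 TPM, Agr2 at 378 ± 36.4 TPM and the mucin Muc2 at 137 ± 4.77 TPM. The goblet list stood 25.7-fold (log2 4.68 ± 0.051) above the Paneth list. Lyz1, the Paneth cell lysozyme, was at 6.95 ± 1.11 TPM, a ratio of Muc2 to Lyz1 of 19.6-fold (log2 4.30 ± 0.28). Defensin genes were nevertheless detected: Defa24 at 602 ± 0.714 TPM, Defa17 at 249.9 ± 11.5 TPM and Defa3 at 40.6 ± 1.99 TPM, while Defa22 and Defa5 were under 0.1 TPM in both pups. These copies are near-identical, so how the reads divide between them is uncertain. Ang4, another Paneth gene, was at 7.83 ± 2.91 TPM. Gut hormones were led by Sct, secretin, at 286 ± 12.5 TPM, Pyy at 146 ± 6.22 TPM, Nts at 123 ± 0.629 TPM and Gip at 118 ± 3.71 TPM. The granule protein Chga (33.8 ± 0.806 TPM) exceeded the endocrine progenitor factor Neurog3 (1.14 ± 0.0990 TPM) by 27.4-fold (log2 4.78 ± 0.081). The absorptive enterocyte list, led by Fabp2, Fabp1 and Rbp2, had a median of 125 ± 3.91 TPM, and its contrast with the goblet list was log2 1.08 ± 0.29, whose sign changed (-0.092) when only members at 1 TPM or more were kept.

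Tuft cell genes were sparse. Only 3 of 13 members passed 1 TPM in both pups, Ptgs1 (24.2 ± 0.742 TPM), Alox5ap (2.65 ± 0.332 TPM) and Dclk1 (2.29 ± 0.163 TPM), with Trpm5 at 0.945 ± 0.205 TPM, and Il25 and Sh2d7 were under 0.1 TPM in both. All 16 crypt and stem cell genes passed 1 TPM. Smoc2 stood at 49.1 ± 0.827 TPM, Cdca7 at 26.4 ± 0.509 TPM, Olfm4 at 21.1 ± 1.58 TPM and Slc12a2 at 14.6 ± 0.396 TPM. Proliferation genes had a median of 29.8 ± 2.58 TPM, with Cdk1 at 93.4 ± 19.1 TPM, Pcna at 84.4 ± 0.969 TPM, Birc5 at 68.2 ± 1.20 TPM and Tyms at 52.8 ± 1.55 TPM. Of the fetal epithelial genes, 8 of 11 passed 1 TPM. Krt7 stood at 68.1 ± 1.57 TPM, Anxa1 at 38.3 ± 1.39 TPM, Ly6a at 36.2 ± 0.983 TPM and Gja1 at 24.1 ± 0.750 TPM, and Lin28b was under 0.1 TPM in both pups.

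**Figure D1:**
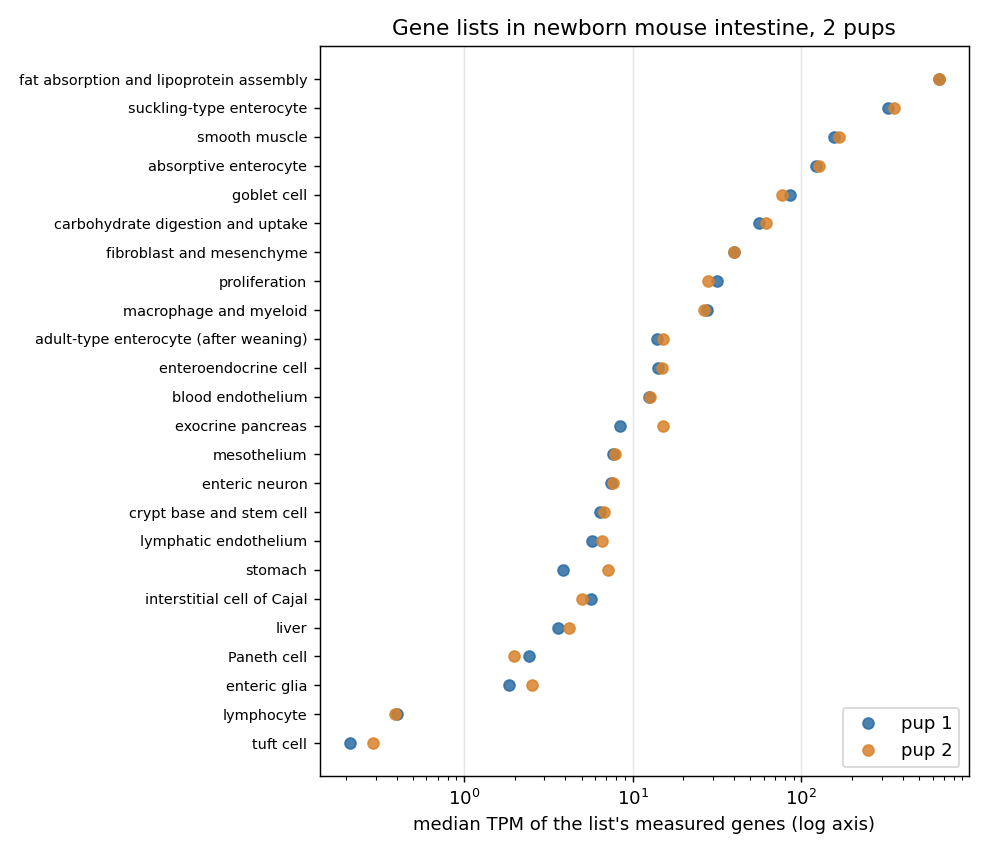
Median TPM of the measured genes of selected lists (horizontal log axis) in pup 1 and pup 2, 1 point per pup, ordered by their mean. Fat absorption lies at the top at 654 ± 2.58 TPM, and the lymphocyte list, at 0.395 ± 0.00707 TPM, is among the lowest.

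Smooth muscle and mesenchyme genes were also abundant. Actg2, the smooth muscle actin of the gut, stood at 1869 ± 61.7 TPM, Acta2 at 1426 ± 37.3 TPM, the myosin light chain Myl9 at 1082 ± 31.2 TPM and Tpm2 at 792 ± 66.8 TPM. Actg2 exceeded Acta2 by 1.31-fold (log2 0.39 ± 0.0099), an order that turned (-0.086) without length normalisation. The smooth muscle list had a median of 161 ± 7.43 TPM, and the enterocyte list stood at log2 -0.34 ± 0.030 relative to it, which changed sign (0.82) when means replaced medians. Collagens led the fibroblast list, with Col3a1 at 476 ± 11.5 TPM, Col1a1 at 283 ± 16.7 TPM and Col1a2 at 158 ± 4.36 TPM, beside the proteoglycan Dcn at 265 ± 0.594 TPM. Basement membrane genes were led by Col4a1 (65.8 ± 1.04 TPM), Col4a2 (35.9 ± 0.0354 TPM), Lamc1 (33.5 ± 2.99 TPM) and Lamb1 (26.2 ± 0.0778 TPM). Mesothelial Msln and Upk3b stood at 38.3 ± 3.54 and 24.0 ± 2.59 TPM, with Upk1b at 10.3 ± 0.276 TPM, Lrrn4 at 7.75 ± 0.127 TPM and Tbx18 under 0.1 TPM in both pups.

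Enteric neurons and glia, pacemaker cells and vessels were each represented. The neuronal list had 16 of 20 genes at 1 TPM or more, with Uchl1 at 54.8 ± 3.61 TPM, the neuropeptide Gal at 35.3 ± 1.92 TPM, Gap43 at 32 ± 0.325 TPM and Stmn2 at 32.0 ± 2.28 TPM. Smooth muscle genes exceeded it by 20.9-fold (log2 4.39 ± 0.032). Glial genes were lower, with 6 of 10 at 1 TPM or more, and the neuronal list stood 3.38-fold (log2 1.76 ± 0.28) above the glial one, falling to log2 0.41 when only members at 1 TPM or more were kept. Ednrb (51.6 ± 0.728 TPM), Fabp7 (23.0 ± 1.07 TPM), Erbb3 (18.5 ± 0.863 TPM) and S100b (5.17 ± 0.658 TPM) led the glial list. All 5 genes of interstitial cells of Cajal passed 1 TPM, led by Etv1 (14.2 ± 0.127 TPM) and the chloride channel Ano1 (7.22 ± 0.163 TPM), then Thbs4 (5.37 ± 0.460 TPM) and the receptor Kit (4.67 ± 0.0919 TPM). Plvap (87.5 ± 0.976 TPM), Egfl7 (48.1 ± 6.21 TPM), Esam (22.5 ± 0.679 TPM) and Pecam1 (20.9 ± 0.106 TPM) led the blood endothelial list, and Ccl21a (58.1 ± 1.27 TPM), Lyve1 (21.4 ± 1.00 TPM), Pdpn (14.7 ± 0.226 TPM) and Mmrn1 (6.17 ± 0.629 TPM) the lymphatic list.

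Myeloid genes were expressed and most lymphocyte genes stayed under 1 TPM. The macrophage and myeloid list stood 52.9-fold (log2 5.73 ± 0.027) above the lymphocyte list. This contrast fell to log2 3.79 when only members at 1 TPM or more were kept, 4.28 with a pseudocount of 1 TPM and 4.39 with means over members. The receptor Csf1r stood at 80.2 ± 3.01 TPM, C1qb at 55.8 ± 2.14 TPM, Tyrobp at 49.4 ± 2.14 TPM and Fcer1g at 40.8 ± 3.57 TPM. Of the lymphocyte genes 4 of 15 passed 1 TPM. These included Ighm (2.75 ± 0.156 TPM), Ptprcap (2.19 ± 0.184 TPM) and Cd79b (1.16 ± 0.0919 TPM), and Cd8a and Jchain were under 0.1 TPM in both pups. Granulocyte and mast cell genes were low, led by Tpsb2 (5.83 ± 0.636 TPM), Ltf (5.66 ± 0.636 TPM), Cma1 (4.89 ± 0.346 TPM) and S100a8 (3.85 ± 1.41 TPM), and Elane had no read. Interferon-response genes were expressed, with 11 of 14 at 1 TPM or more and Irf7 at 99.3 ± 2.28 TPM, Bst2 at 73.1 ± 3.80 TPM, Ifit1 at 71.3 ± 2.11 TPM and Oasl2 at 65.8 ± 5.83 TPM. Class I genes B2m (1681 ± 97.1 TPM), H2-K1 (606 ± 23.9 TPM) and H2-D1 (544 ± 5.17 TPM) led the MHC list, and the class II chaperone Cd74 stood at 84.2 ± 0.940 TPM. Defence genes were led by the chemokine Ccl25 (162 ± 14.7 TPM), Reg3b (60.4 ± 24.2 TPM), Myd88 (24.3 ± 0.679 TPM) and Ccl20 (16.6 ± 8.50 TPM), and Reg3a and Tlr9 were under 0.1 TPM.

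Adult globins were present and embryonic globins near the floor. Hba-a2 stood at 907 ± 264 TPM, Hbb-bs at 605 ± 177 TPM, Hba-a1 at 401 ± 119.5 TPM and Hbb-bt at 225 ± 48.1 TPM, the paired copies sharing reads. Hbb-y, an embryonic globin, had expected counts of 8 and 2 in pups 1 and 2, Hba-x (0.135 ± 0.0778 TPM) 4 and 1, and Hbb-bh1 had none. The ratio of Hbb-bs to Hbb-y was 959-fold in pup 1 and 3176-fold in pup 2 (log2 10.77 ± 1.22).

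Regulators of intestinal identity were expressed broadly, 25 of 26 at 1 TPM or more. Creb3l3, a regulator of lipid metabolism, stood at 313 ± 6.10 TPM, Elf3 at 129.97 ± 2.67 TPM, the bile acid receptor Nr1h4 at 103 ± 12.1 TPM and the homeobox factor Cdx1 at 97.5 ± 1.66 TPM. Cdx1 exceeded Cdx2 (29.7 ± 2.25 TPM) by 3.28-fold (log2 -1.72 ± 0.13), the log2 value being that of Cdx2 over Cdx1. Hnf4a (41.6 ± 1.22 TPM) and Hnf4g (44.6 ± 4.58 TPM) differed by less than the spread between pups (log2 -0.098 ± 0.11), and without length normalisation their log2 ratio was 0.74. Gata6 (41.4 ± 3.39 TPM) exceeded Gata4 (25.6 ± 3.80 TPM) by 1.62-fold (log2 0.70 ± 0.096). Of the hedgehog ligands, Ihh (20.2 ± 0.205 TPM) exceeded Shh (0.170 ± 0.0283 TPM) by 75.2-fold (log2 -6.23 ± 0.17), the log2 value being that of Shh over Ihh. With a pseudocount of 1 TPM that log2 value was -4.18. The signalling list was led by Hes1 (39.0 ± 5.11 TPM), Bmp7 (31.3 ± 2.12 TPM), Sfrp1 (22.6 ± 3.74 TPM) and Ihh, with 25 of 30 genes at 1 TPM or more. Imprinted growth genes were high, with H19 at 545 ± 30.2 TPM, Igf2 at 387 ± 8.37 TPM, Cdkn1c at 338 ± 31.0 TPM and Mest at 132 ± 7.59 TPM, and H19 exceeded Igf2 by 1.41-fold (log2 -0.49 ± 0.049), the log2 value being that of Igf2 over H19.

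HOX genes, which mark position along the body axis, were expressed in both pups in paralogue groups 2 to 8, and those of the posterior groups differed between the pups. Summed over groups 1 to 8, they came to 78.2 ± 2.50 TPM, and pup 2 stood at 1.03-fold of pup 1 (exact 95% interval 0.982 to 1.07). Summed over groups 9 to 13, pup 1 had 14.5 TPM and pup 2 2.41 TPM, and pup 1 was higher by 7.03-fold (exact 95% interval 5.77 to 8.64). The 15 genes at 1 TPM or more in both pups were Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxa7, Hoxb2, Hoxb5, Hoxb6, Hoxb7, Hoxc4, Hoxc5, Hoxc6, Hoxc8, Hoxd3 and Hoxd8, from 1.95 ± 0.290 TPM for Hoxd8 to 12.3 ± 0.594 TPM for Hoxb5. Hoxa13, Hoxb1, Hoxb13 and Hoxc11 were among the 9 under 0.1 TPM in both. Hoxa10 (ENSMUSG00000000938.11, chromosome 6, 52231197 to 52240854) had expected counts of 377 and 6 in pups 1 and 2 and was 50.1-fold (95% interval 22.8 to 137) higher in pup 1. Hoxa11 had 70.7 and 0, at least 18.9-fold higher in pup 1 against a floor of 3 counts per library, with an exact 95% lower limit of 14.95-fold. The strand used in counting is not given in the sources used here, so reads of Hoxa11 and its antisense partner cannot be told apart.

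**Figure D2:**
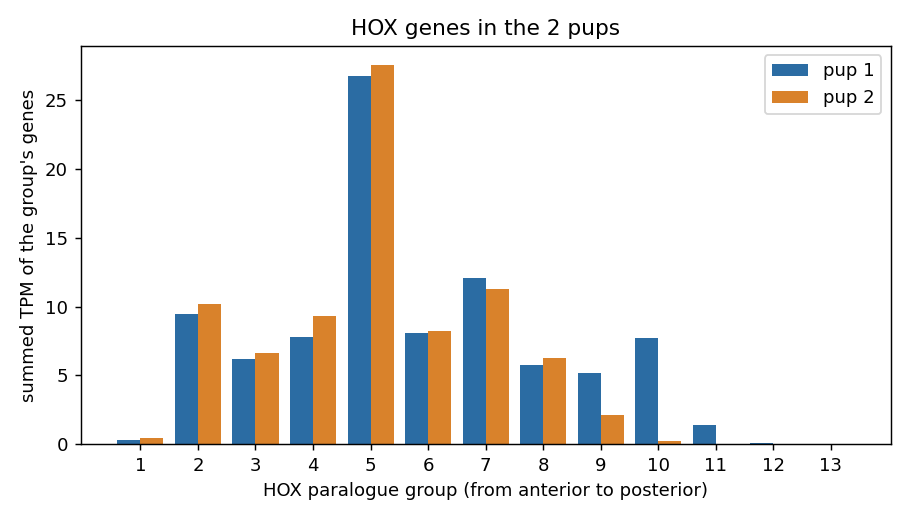
Summed TPM of the HOX genes of each paralogue group, 1 bar per pup, groups ordered from anterior to posterior. The bars of both pups are of similar height in groups 1 to 8, and in group 10 pup 1 reached 7.74 TPM against 0.260 TPM in pup 2.

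Marker genes of the upper small intestine stood above those of the colon in both pups. The duodenum and jejunum list, led by the iron exporter Slc40a1 (453 ± 44.96 TPM), Sct, Gip and Lct, stood above the colon list by 12.8-fold in pup 1 and 61.5-fold in pup 2 (log2 4.81 ± 1.60). With members at 1 TPM or more alone this fell to log2 1.57. In the ileum list, led by Guca2a, the bile acid exporters Slc51b (285 ± 32.1 TPM) and Slc51a (250.2 ± 29.3 TPM) and Nts, Fabp6, the bile acid binding protein, was at 86.6 ± 22.2 TPM, and Fabp1 exceeded it by 143-fold (log2 7.16 ± 0.32). In the colon list Mettl7b (194 ± 10.2 TPM), Prr15l (112 ± 1.80 TPM), Slc26a3 (54.7 ± 7.71 TPM) and Aqp8 (21.8 ± 4.36 TPM) led, and Hoxa13, Hoxb13, Hoxd13 and Hoxd12 were under 0.1 TPM.

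Genes listed for neighbouring tissues were expressed unevenly, and which cells held their RNA was not tested. Enterocyte genes exceeded the exocrine pancreas list by 14.4-fold in pup 1 and 8.38-fold in pup 2 (log2 3.46 ± 0.55) and the liver list by 41.1-fold (log2 5.36 ± 0.093). The liver value reversed to -0.51 when only members at 1 TPM or more were kept. Clps (104 ± 13.4 TPM), Ctrb1 (77.0 ± 23.6 TPM), Cela2a (41 ± 16.8 TPM) and Rnase1 (18.1 ± 0.742 TPM) led the pancreatic list, and Pnlip was under 0.1 TPM. Afp (489 ± 87.4 TPM), alpha-fetoprotein, exceeded Alb (0.825 ± 0.0495 TPM), albumin, by 525-fold (log2 9.04 ± 0.18), and Ttr (322 ± 17.7 TPM), Trf (196 ± 4.05 TPM) and Cps1 (184 ± 13.3 TPM) were the other liver-list genes over 100 TPM. In the stomach list Tff1 (137 ± 122 TPM), Tff2 (128 ± 49.0 TPM), Gkn3 (41.0 ± 15.7 TPM) and Gkn2 (27.2 ± 29.8 TPM) led, and Muc5ac, Atp4b, Gif and Chia1 were under 0.1 TPM. Of the adipose genes Cidec (194 ± 15.9 TPM), Fabp4 (167 ± 15.1 TPM) and Cidea (1.35 ± 0.106 TPM) passed 1 TPM, while Adipoq, Plin1, Ucp1 and Cfd were at 0 in both pups. Skeletal muscle genes were low, led by Ckm (16.2 ± 0.247 TPM), Mylpf (8.27 ± 0.622 TPM), Myl1 (7.61 ± 0.969 TPM) and Acta1 (4.19 ± 2.77 TPM).

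The 2 pups matched closely for most genes and differed in small groups of genes. After scaling by TMM (trimmed mean of M-values), 16875 of 17094 genes with a count of 10 or more in both pups lay within 2-fold, and the common biological coefficient of variation was 7.93%. The counts differed by more than sampling noise (chi-square of 11.9 per degree of freedom over 19088 genes), and each library was counted as 1 replicate. Of 19088 genes with a summed count of 10 or more, 83 were over 2-fold higher in pup 2 and 70 in pup 1, by exact 95% intervals lying wholly beyond 2-fold. Of these 153 genes, 89 were protein-coding and 31 were pseudogenes, which can share reads with their parent genes. Posterior mean counts gave 82, and scaling on the spike-in total, which rests on 534 and 200 reads, gave 5580 higher in pup 2 and 23 in pup 1, after a shift of all genes by 1.09 (log2), so ratios towards pup 1 smaller than this shift turn under that scaling. The log2 ratio of pup 2 over pup 1 rose with gene length across 14985 protein-coding genes, which are not independent replicates (Spearman 0.194), with medians from -0.049 to 0.097 over 20 bins of length. These comparisons concern the libraries, not conditions.

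Genes of the stomach were prominent among those higher in pup 2. Genes over 2-fold apart with a summed count of 50 or more were ranked, without those having no symbol or a predicted-gene name (Gm or Rik). Of these, the 10 highest ratios were those of Rnu3b1 and Rnu3b3, Muc5b, Bpifb1, Gkn2, Psca, Cldn18, Gkn1, Barx1 and Mucl3. Predicted genes left out, such as Gm4613 (0 and 54 counts) and Gm26602 (7 and 62), had ratios above those of several of these. Gkn2 (ENSMUSG00000030049.4, chromosome 6, 87373357 to 87379497), a gastrokine of gastric surface cells, had expected counts of 149 and 902 and was 7.59-fold (95% interval 6.38 to 9.09) higher in pup 2. Bpifb1, a secreted protein of mucosal surfaces, was 7.79-fold (95% interval 6.61 to 9.22) higher, Cldn18, a claudin of stomach and lung, 6.31-fold (95% interval 4.99 to 8.08), and Barx1, a homeobox gene of the stomach mesenchyme, 6.73-fold (95% interval 3.50 to 14.2). The mucin Muc5b (14.2-fold), Psca (7.05-fold), Gkn1 (6.16-fold) and Mucl3 (5.66-fold) were also higher in pup 2. The U3 RNA copies Rnu3b1 and Rnu3b3, each with 0 and 59.8 counts, were at least 25.1-fold higher against the floor of 3 counts (exact 95% lower limit 19.8-fold), but are near-identical, so the split of their reads is uncertain. The stomach list had a median log2 ratio of pup 2 over pup 1 of 1.21, at percentile 100 of 10000 random lists matched on expression, with intervals above 1 for 8 of 12 members with reads. Among these, Tff1, a trefoil peptide, was 4.25-fold (95% interval 3.91 to 4.64) higher, the pepsinogen Pgc 3.21-fold (95% interval 2.79 to 3.70) and the hormone gastrin, Gast, 4.18-fold (95% interval 2.15 to 8.75). The mucin Muc6 and the proton pump gene Atp4a stood lower in pup 2, at 0.879-fold (95% interval 0.825 to 0.937) and 0.369-fold (95% interval 0.163 to 0.764) of pup 1.

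HOX genes of the posterior groups and Car1 were prominent among those higher in pup 1. The 10 lowest ratios under the same rule, without predicted genes, were those of Car1, Gvin1, Hoxa10, Hoxa11, Foxd2os, Hoxd10, Duxbl3, Hoxa9, Fa2h and Krtap26-1. Predicted genes left out, such as Gm26825 (113 and 0 counts) and Gm14549 (73 and 0), had ratios below those of several of these. Car1 (ENSMUSG00000027556.11, chromosome 3, 14766216 to 14808368), a carbonic anhydrase of the large intestine, had expected counts of 235 and 0, at least 62.5-fold higher in pup 1 against the floor of 3 counts in pup 2, with an exact 95% lower limit of 50.4-fold. Hoxd10 was 16.1-fold (95% interval 6.07 to 60.7) higher, Hoxa9 6.56-fold (95% interval 4.01 to 11.4), the lipid hydroxylase Fa2h 5.46-fold (95% interval 3.60 to 8.59), the antisense transcript Foxd2os 22.7-fold (95% interval 6.01 to 192) and Krtap26-1 5.70-fold. These folds are of counts, and in TPM the difference was smaller for Hoxa9 (2.34 and 0.850 TPM). Gvin1 (155 and 0 counts) was at least 41.2-fold higher (exact 95% lower limit 33.1-fold) and Duxbl3 13.8-fold (95% interval 4.48 to 69.2) by counts and less by TPM, but both belong to families of near-identical copies and are uncertain.

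**Figure D3:**
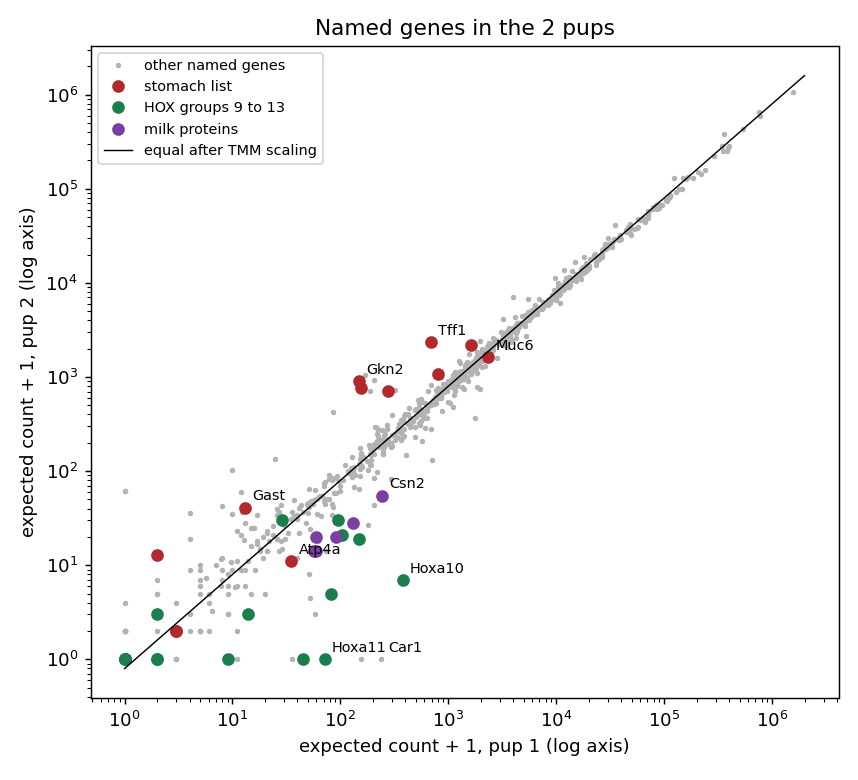
Expected count + 1 of the named genes in pup 1 (horizontal log axis) and pup 2 (vertical log axis), 1 point per gene, with the line of equal expression after TMM scaling. Most stomach genes, such as Gkn2 (149 and 902 counts), lie above the line, and most HOX genes of groups 9 to 13, such as Hoxa10 (377 and 6), and the milk-protein genes, chosen after their values were seen, such as Csn2 (240 and 54), below it. Muc6 and Atp4a of the stomach list lie below it too.

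Of 53 gene lists with 3 or more members with reads, 9 had a median ratio above the 99th percentile of matched random lists and 7 below the 1st, where 1.06 in all would be outside if the members varied independently. Member counts are to be read against a background: of all 19088 genes tested, 14.2% had an interval above 1 and 15.5% below. Intervals cover counting error only, so those of abundant genes are narrow and can exclude 1 at small differences. Higher in pup 2 were exocrine pancreas (median log2 ratio 0.48, intervals above 1 for 12 of 17 members), erythroid (0.47, 6 of 11) and abundant nuclear lncRNA (0.37, 6 of 8). No interval of the first 2 lay below 1, against 2 of 8 of the lncRNA list. Ctrb1, chymotrypsinogen, was 1.49-fold (95% interval 1.40 to 1.59) higher, Hba-a2 1.46-fold (95% interval 1.42 to 1.496), Malat1 1.46-fold (95% interval 1.44 to 1.48) and Neat1 1.39-fold (95% interval 1.36 to 1.43). The lists of smooth muscle (0.070), protein digestion (0.071), duodenum and jejunum (0.092), suckling-type enterocyte (0.042) and sex-linked genes (0.11) were also above the 99th percentile with medians near 0. In these the intervals below 1 numbered 1 of 16, 1 of 12, 4 of 12, 4 of 18 and 1 of 8. The random lists were matched on expression and not on gene length, and these medians are of the size of the length trend. With that trend removed, a test chosen after the data were seen, 14 of the 16 lists stayed outside on the same side, and duodenum and jejunum (percentile 96.6) and sex-linked (percentile 90.2) did not. The duodenum and jejunum call was also lost (0.045) without members at low counts, and the sex-linked call with spike-in scaling (percentile 96.9) and with log2(TPM + 1) (percentile 94.7). Higher in pup 1 were goblet cell (median log2 ratio -0.32, intervals below 1 for 11 of 14 members), glucocorticoid and fasting response (-0.38, 6 of 11) and Paneth cell (-0.28, 3 of 11). Members also went the other way, with intervals above 1 for 2 of 14, 4 of 11 and 1 of 11, and the summed TPM of the glucocorticoid and fasting list was 2370.3 in pup 1 and 2579 in pup 2. The Paneth call was lost (-0.16, percentile 2.71) without members at low counts. Klk1 was 1.61-fold (95% interval 1.43 to 1.81) higher in pup 1, Spink4 1.52-fold (95% interval 1.45 to 1.59), Atoh1, the factor that specifies secretory cells, 1.70-fold (95% interval 1.45 to 2.00), Pdk4 2.10-fold (95% interval 1.93 to 2.28) and the clock gene Per1 1.82-fold (95% interval 1.64 to 2.03), while Pck1 of the fasting list was among those higher in pup 2 (1.29-fold). With spike-in scaling the medians of all 7 lists higher in pup 1 turned positive, from 0.71 for goblet cell to 0.99 for proliferation, all below the shift of 1.09 for all genes, and they kept their side of the matched random lists. Proliferation (-0.10), nuclear respiratory chain (-0.13), fat absorption (-0.13) and interferon response (-0.11) were below the 1st percentile with medians nearer 0, and 0 of 18, 0 of 17, 4 of 18 and 1 of 14 of their members had an interval above 1. Cyc1 of the respiratory chain was 1.24-fold (95% interval 1.21 to 1.27) higher in pup 1, Ccnb1, the mitotic cyclin, 1.43-fold (95% interval 1.34 to 1.52) and Usp18, an interferon-induced protease, 1.57-fold (95% interval 1.41 to 1.75).

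Genes of both sex chromosomes gave the same picture in both pups. Xist, the RNA that coats the inactive X chromosome, stood at 20.97 and 25.0 TPM in pups 1 and 2, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had at most 1 read in each pup. The X-linked Ddx3x (71.1 ± 4.55 TPM), Eif2s3x (28.8 ± 0.856 TPM) and Kdm5c (14.7 ± 2.05 TPM) were expressed in both. Xist and Tsix (12.7 ± 3.49 TPM) overlap on opposite strands. Nuclear protein-coding genes took 89.1 ± 0.233% of the counts and the 13 mitochondrial mRNA genes 3.87 ± 0.162%. The highest of these, mt-Atp6 (17664 ± 1303 TPM), shares reads with nuclear copies of mitochondrial sequence, which took a further 1.48 ± 0.0811%. Of the RNAs without a poly(A) tail, the highest were Rn7s1 (15362 ± 449 TPM) and Rn7s2 (15362 ± 450.1 TPM), near-identical copies of the signal recognition particle RNA whose reads cannot be split, followed by Hist1h2bc (295 ± 11.9 TPM) and Rn7sk (257 ± 49.6 TPM).

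The most abundant transcript of a gene was the same in both pups for most genes. This was examined in 9131 genes with 2 or more annotated transcripts and an expected count of 100 or more in both pups. Of these, 8418 (92.2%) had the same most abundant transcript in both. Genes of the same libraries are not independent replicates, so no interval is given for this percentage. The deposited share of a transcript in its gene differed between pups by a median of 2.06 percentage points over 29793 transcripts. Spike-in transcripts were few: 5 of them had a count of 10 or more in both pups. The SD of their log2 ratio, from these 5 values, was 0.295, against 0.416 for 1816 genes. The counts compared were similar in pup 1 (48 to 123). In pup 2 spike-ins stood at 0.480-fold by share of reads, so the counts there were less alike.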

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

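Removal of the gene-length trend was chosen after the result was seen, and the other alternatives here were planned. The count of detected genes, 13870, stayed within 1.5 times under all 7 alternatives, from 9549 at 5 TPM to 16538 with posterior mean TPM. The 20 genes named for the highest and lowest ratios, predicted genes left out, were chosen for them, so that none turned under an alternative says nothing of stability. For these, log2(TPM + 1) brought the ratios of genes of low TPM nearer 0, such as Muc5b (0.29 from 3.54) and Gvin1 (-0.58 from -6.14). Leaving out a pup moves a mean of 2 values by a fixed fraction of their SD, so it says nothing of stability. Leaving out shared members gave no value, since no contrast had any, and neither did a spike-in minimum of 50 counts, which no spike-in reached. Low reads limit spike-ins, embryonic globins and posterior HOX genes in pup 2. The cause of the changes below was not tested, except where fewer genes or another threshold sets a count.

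With means over members, the log2 contrast became 1.97 for enterocyte over goblet, 0.82 (reversed) for enterocyte over smooth muscle, 4.70 for fat over carbohydrate, 4.27 for suckling over adult type, 3.82 for goblet over Paneth and 4.22 for muscle over neuron. It became 1.19 for neuron over glia, 4.39 for myeloid over lymphocyte, 4.62 for enterocyte over pancreas and 4.63 for enterocyte over liver. With members at 1 TPM or more, enterocyte over goblet (-0.092) and over liver (-0.51) reversed, since members under 1 TPM dropped out. The others were -0.30 for enterocyte over smooth muscle, 4.20 for suckling over adult type, 4.18 for goblet over Paneth, 3.60 for muscle over neuron, 0.41 for neuron over glia, 3.79 for myeloid over lymphocyte and 1.57 for duodenum and jejunum over colon. With a pseudocount of 1 TPM, suckling over adult type was 4.44, goblet over Paneth 4.24, muscle over neuron 4.23, neuron over glia 1.43, myeloid over lymphocyte 4.28 and enterocyte over liver 4.92. Posterior mean TPM gave 4.55 for goblet over Paneth and 5.68 for myeloid over lymphocyte.

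Of the pairs, a pseudocount of 1 TPM gave 4.95 for Lct over Sis, 5.19 for Lct over Treh, 7.84 for Ass1 over Arg2, 8.88 for Hbb-bs over Hbb-y, 8.06 for Afp over Alb, 4.02 for Chga over Neurog3 and -4.18 for Shh over Ihh. Posterior mean TPM gave 5.60 for Lct over Treh. Without length normalisation, Actg2 over Acta2 (-0.086) and Hnf4a over Hnf4g (0.74) reversed. The others were 6.80 for Lct over Sis, 7.42 for Lct over Treh, 9.10 for Ass1 over Arg2, 0.93 for Apoa4 over Apoa1, 4.60 for Muc2 over Lyz1, -0.69 for Igf2 over H19, -1.33 for Cdx2 over Cdx1, 1.16 for Gata6 over Gata4 and 5.09 for Chga over Neurog3.

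Between pups, genes over 2-fold apart numbered 23 at a count of 50 or more in both, 89 among protein-coding genes, 82 with posterior mean counts, 283 at 1.5-fold and 5603 with spike-in scaling, where 99.6% were higher in pup 2 against 54.2% with TMM. The BCV became 0.520 with spike-in scaling, which shifts all genes alike. That shift turned the list ratios of fat absorption (0.96), goblet (0.71), Paneth (0.72), proliferation (0.99), interferon (0.98), glucocorticoid (0.71) and respiratory chain (0.96) positive. Of the 16 lists outside the 1st to 99th percentile, 15 stayed there with spike-in scaling and with log2(TPM + 1), sex-linked (1.12 and 0.094) being the exception in both. With members at 10 counts or more, 14 stayed, the exceptions being Paneth (-0.16) and duodenum and jejunum (0.045). With the gene-length trend removed, 14 stayed, the exceptions being duodenum and jejunum (0.062) and sex-linked (0.040). The same top transcript was found for 95.4% of genes at 1000 counts or more and 97.8% where it held 60% or more.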

Other observations

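In this part, the removal of a gene-length trend was chosen after the results were seen. Immediate early genes were at moderate levels, with Zfp36 (68.7 ± 2.69 TPM), Ier2 (62.9 ± 1.20 TPM), Jun (48.8 ± 2.81 TPM) and Junb (35.7 ± 2.59 TPM) leading a list of which 12 of 14 members reached 1 TPM in both pups. The list had a between-pup median log2 ratio of 0.0019. Of the clock genes 13 of 14 reached 1 TPM, led by Cry1 (15.7 ± 0.940 TPM), Tef (11.8 ± 1.48 TPM), Cry2 (8.66 ± 0.976 TPM) and Per1 (7.05 ± 2.21 TPM). Mt1, a metallothionein of the fasting list, stood at 1761 ± 112 TPM. Ribosomal protein genes had a median of 477 ± 2.17 TPM, led by Rpl32 (1102 ± 2.15 TPM), Rps14 (1093 ± 15.2 TPM), Rps18 (837 ± 5.25 TPM) and Rpl7 (759 ± 6.41 TPM), and nuclear respiratory chain genes a median of 488 ± 22.3 TPM, led by Atp5b (2012 ± 103 TPM). The mitochondrial rRNAs mt-Rnr2 (15188 ± 1221 TPM) and mt-Rnr1 (4741 ± 1027 TPM) were the only members of their list.

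Further genes were chosen after their values were seen. Cym, the milk-clotting protease chymosin, was 2.26-fold (95% interval 2.18 to 2.35) higher in pup 2, the pepsinogen Pga5 4.75-fold (95% interval 4.04 to 5.61), the protease Ctse 2.86-fold (95% interval 2.50 to 3.27) and the anion transporter Slc26a9 14.6-fold (95% interval 4.61 to 74.4). Slc6a14, an amino acid transporter, was 3.79-fold (95% interval 3.38 to 4.25) higher in pup 1, Cyp2c55 4.29-fold (95% interval 3.55 to 5.20) and Hsd11b2, which inactivates glucocorticoids, 3.80-fold (95% interval 2.73 to 5.41). By point values, the islet hormone genes Ins2 (2.19-fold), Ins1 (1.97-fold), Iapp (1.86-fold) and Ppy (2.83-fold) were higher in pup 1, whereas the exocrine pancreas list was higher in pup 2. None of these islet genes was among those counted as over 2-fold apart. Gm42418, which overlaps rRNA sequence, took 0.811% and 1.11% of the counts, and spike-ins were 0.480-fold in pup 2 relative to pup 1 by share of reads (exact 95% interval 0.406 to 0.565).

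No biological explanation was tested for the 3 patterns weighed here, since the design has 1 group. The first pattern is the higher level of stomach genes in pup 2. The gene-length trend (bin medians from -0.049 to 0.097) is too small to account for the stomach list's median log2 ratio of 1.21. Its removal, which left 1.25, could not have come out otherwise and is no separate test. Stomach tissue in the pup 2 sample may contribute and stays open. A second list of 17 stomach and pylorus genes, none in an earlier list, had a median log2 ratio of -0.23 at percentile 3.22, which met the bound written against this source, but only 2 members reached 1 TPM in both pups and members went both ways, so under a rule added after the value was seen it was not taken as decisive. Intervals lay above 1 for Nkx2-5 (3 and 18 reads) and Slc5a5 (16 and 33) and below 1 for Lipf (83 and 33), Nkx3-2 (65 and 32) and Krt14 (438 and 296). Of all 19088 genes tested, 14.2% had an interval above 1 and 15.5% below, so 2 and 3 of 17 members decide nothing. Gast, Barx1, Cym, Pga5 and Ctse, which are not in that list, were higher in pup 2. Gast belongs to the first stomach list, Barx1 was named for its high ratio and the others were chosen after their values were seen. These genes are therefore part of the pattern and no evidence for its source.

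The second pattern is the higher level of posterior HOX genes and Car1 in pup 1. The median log2 ratio of the HOX genes of groups 9 to 13 was -1.95 before and -1.94 after the gene-length trend was removed. That trend (bin medians from -0.049 to 0.097) is too small to account for this median, so its removal is no separate test here either. A candidate explanation is that the pup 1 sample held more tissue from the caecum and colon end. A second list of 18 caecum and colon genes, none in an earlier list, had a median log2 ratio of -0.47 at percentile 0 of matched random lists, with 10 of 17 members with reads having an interval below 1. The colon list fixed earlier had a median of -0.17 at percentile 2.37, not outside the 1st (0.820 with the length trend removed), with 5 intervals below and 2 above 1 among 13, and a summed TPM of 404 in pup 1 and 412 in pup 2. Of the second list's members 8 were at 1 TPM or more in both pups, Lypd8 highest (1272 ± 149.6 TPM), so the tissue expresses them in any case, and Hoxa11os shares its locus with Hoxa11; a difference between the pups themselves stays open.

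The third pattern is milk-protein RNA, noticed after the values were seen: Csn1s1, Csn1s2a, Csn2, Csn3, Wap and Glycam1 had 632 reads in pup 1 and 145 in pup 2, 3.48-fold higher in pup 1 (exact 95% interval 2.90 to 4.19), Csn2 at 6.54 and 1.92 TPM. One outside source of mammary RNA may account for it, which stays open. A second list of 6 mammary genes met the bound written against this source, at 1.15-fold (0.891 to 1.498), but Olah held 87.3% of its reads, so under a rule added after the value was seen it was not taken as decisive. Without Olah it was 1.75-fold (0.797 to 4.15, 22 against 10 reads), which holds both 1 and the milk-protein fold. Of 9 genes of other organs, 1, Neurod6, had 10 or more reads in pup 1. This met the bound written against reads from several other tissues. The milk-protein genes themselves had only 56 to 240 reads in pup 1, so less abundant genes of other organs could stay under 10 reads. The count therefore cannot exclude reads from several other tissues, which stay open. Ingested milk and a mammary library alone, neither of them tested, stay open too.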
